A study of Mus musculus with 2 samples.

How the data were processed

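Gene expression was measured in CD34-positive tumour epithelial cells sorted from chemically induced skin tumours of mice, with 1 Affymetrix Mouse Genome 430 2.0 array for a wild-type animal and 1 for a K14CreER:Rosa-VEGF-164 animal. This array carries short oligonucleotide probes grouped into probe sets that read mainly the 3′ end of transcripts. Per the labels, 100 ng of total RNA with bacterial spike-in controls was amplified and labelled with a 3′ in vitro transcription kit. The cells had been released with collagenase, stained and sorted by flow cytometry as living cells, using CD34, α6-integrin and Epcam antibodies and a shared dye for CD45, CD31 and CD140a, per the labels.

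The deposited values are log2 signals, and the submitters' processing notes name MAS5, a method that summarises each probe set separately on each array. The software version and the scaling target are not given in the sources used here. The anti-logged signals had a 2% trimmed mean of 100.04 on both arrays, so the arrays share a common global scale. This scaling fixes the average and not the low end of the scale: the median signal was 22.6 on the wild-type array and 17.3 on the array labelled VEGF. Detection calls and probe-level data were not analysed here.

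The table held 45101 probe sets, of which 64 were controls. A platform annotation gave exactly 1 gene for 34958 probe sets, several genes for 932 and none for 9211. Only the 34958 were used for genes, covering 18193 genes. The gene IDs of 34754 annotated probe sets were found in the GRCm38.p6 gene table, with 0 symbols changed. The annotation does not say which part of a transcript a probe set reads.

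Signals were floored on each array at a background level, the 90th percentile of 80 probe sets of olfactory and vomeronasal receptor genes, genes that skin cells are not expected to use. The level was 19.8 on the wild-type array and 11.3 on the array labelled VEGF, and 20384 and 22793 named probe sets lay above it. A gene took the value of its probe set with the highest mean log2 signal. The log2 ratio is always the array labelled VEGF over the wild-type array. With only 1 array above background the fold is a lower bound against the floor and is written "at least". Genes at or below background on both arrays, and bounds under 1-fold, got no fold. Because the wild-type floor was higher, such bounds arose here only for genes above background on the array labelled VEGF alone. Dropping them was therefore not neutral between the arrays.

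With 1 array per group there is no replicate error, no test between genotypes and no p-value. Genes were counted by a fixed rule of size, a change of at least 2-fold. The only error available was the disagreement between probe sets of the same gene. Across 4885 genes with at least 2 probe sets above background on both arrays, the SD of a single probe set's log2 ratio, taken as the SD of the difference over the square root of 2, was 0.51 in the lowest tertile of signal, 0.40 in the middle and 0.30 in the highest. It covers error that differs between probe sets of the same gene. Labelling or hybridisation effects shared by those probe sets cancel and are not covered, nor is the spread between animals, tumours or sorts.

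A total of 42 lists (27 pathway or state lists and 15 lists of markers of other cell types or of sex) were fixed before the data were examined, as were the background rule, the fold rule, the other settings and the rule for genes named. For each list the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean signal in 20 bins. A list was described as apart when its percentile was below 2.5 or above 97.5. This describes these 2 arrays only. Genes in a list are not independent, so the random lists understate how far a list can move. Lists with fewer than 3 measured members got no percentile. Named genes were a fixed set of VEGF pathway and sort genes, the 12 highest and 12 lowest ratios among genes above background on both arrays, the 4 highest and 4 lowest bounds, and, for each list, the 4 members with the largest ratio in size and the most abundant member. For the highest and lowest ratios and bounds, any other probe set with a fold had to go the same way by at least 0.5 of the log2 ratio. Genes known only by a clone or predicted-gene name were counted and not named. Hras was among the fixed genes and was not analysed here, as it had no probe set of its own in the annotation.

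The other settings were the array median as floor, no floor, an offset of 50 in place of the floor after matching the medians, quantile and loess normalization, median-centred ratios, the median over a gene's probe sets, leaving out probe sets ending in _x_at or _s_at, and a stricter filter (both arrays above background and a mean signal of at least 4 times background). In the setting called no floor, signals below 1 were still raised to 1, and no background filter was used. A floor common to both arrays was added after the data were seen. The procedure was tested on simulated data built from these arrays (200 changed genes among 12556 with a fold). It called 22 of 50 genes with a true 2-fold change, 47 of 50 with a 3-fold change, 50 of 50 with a 4-fold change and 1.45% of unchanged genes. The changed genes were drawn only from genes with a probe set above 4 times background. Both simulated arrays were built around the same mean signals, so they lacked the different low end of the real arrays. The 1.45% is therefore no error rate for the calls made here, least of all at low signal. It placed 4.5% of 200 unchanged lists of 20 genes outside the limits, and all 50 of 50 lists shifted by 0.5 on the log2 scale above them. These lists were drawn at random with independent error for each probe set. The small share of unchanged lists outside was thus built in, and does not cover lists of genes regulated together. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.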

Results

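Mouse skin tumours were induced with DMBA, a polycyclic hydrocarbon carcinogen, given at postnatal days 23, 25 and 27, followed by repeated TPA, a tumour-promoting phorbol ester, and by further DMBA at 7 weeks of age. CD34-positive epithelial cells of these tumours were profiled from a wild-type mouse and from a K14CreER:Rosa-VEGF-164 mouse, which carries a VEGF transgene to be switched on by Cre recombinase in cells that express keratin 14. The design asks which transcripts differ in these cells when VEGF is gained in the epidermis. There was 1 array per genotype, so every value below is a single measurement. Each array held 45101 probe sets, and 58.3% of the named probe sets on the wild-type array and 65.2% on the array labelled VEGF lay above the background level. The log2 signals of the 11233 genes above background on both arrays correlated with r = 0.95 across genes, which are not independent replicates.

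Among 12198 genes with a fold or a bound, 472 were at least 2-fold higher and 1041 at least 2-fold lower on the array labelled VEGF. The higher genes below are the 12 largest ratios whose other probe sets, where present, went along; 5 genes were passed over because theirs did not, among them Ceacam1 at 14.2-fold, named here after its values were seen. The 12 were led by Calcb, the precursor of β-calcitonin gene-related peptide, at 13.7-fold, Baiap2l1, an actin-binding membrane adaptor, at 11.7-fold, and Sncg, a synuclein, at 9.26-fold. Krt18, a keratin of simple epithelia, was 9.14-fold higher with a signal of 1153 against 126. Genes of the cornified layer were among the 12 highest, with Crct1 at 8.83-fold, Sprr2i at 8.71-fold, Tgm3, a transglutaminase that crosslinks the cornified envelope, at 7.12-fold, Sprr2f at 5.95-fold and Sprr1a at 5.84-fold. The remaining 3 of the 12 were the cystine transporter gene Slc7a11 at 7.49-fold, Upk3bl at 7.23-fold and the protease gene Tmprss11e at 6.63-fold. Ppbp, a platelet chemokine, Ltf, which encodes lactoferrin, Lce3c and Sprr3, both of the cornified layer, were above background only on the array labelled VEGF, at least 24.2-, 18.9-, 11.9- and 11.2-fold higher.

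By the same rule, which passed over 2 lower genes, the lowest ratios on the array labelled VEGF were those of Defb6, a β-defensin, 14.4-fold lower, Prss53, 13.8-fold lower, and Prl8a9, 12.3-fold lower. Their signals there (12.8, 13.5 and 16.0) were close to the background of 11.3, and with a floor of 19.8 on both arrays only bounds remain, at least 9.31-, 9.40- and 9.88-fold lower. Lhx2, a transcription factor of hair follicle stem cells, was 11.0-fold lower with a signal of 21.6 against 237. Clca3a2 was 9.70-fold lower, Pgf, a VEGF family ligand, 8.56-fold, Irx4 8.52-fold, Shisa2 7.71-fold and Mmp3, which encodes stromelysin-1, 7.57-fold. Igfbp4, a secreted binder of insulin-like growth factors, was 7.01-fold lower, Pcdhb7 6.94-fold and Apoe, the apolipoprotein E gene, 6.24-fold, with a signal of 896 against 5593. Fgd5, Cited1, Armh4 and Pnmt were above background only on the wild-type array, at least 6.63-, 5.82-, 5.66- and 5.24-fold lower, or 3.79-, 3.33-, 3.23- and 2.99-fold with the common floor. The excess of lower over higher genes varied with the scaling and the signal filter. Higher genes made up 31.2% of those at least 2-fold apart as deposited, 51.1% after quantile normalization, 53.5% after loess normalization, 52.1% with the offset of 50 and 49.9% (297 higher, 298 lower) among genes with a mean signal of at least 4 times background. An excess of lower genes stayed with the common floor (43.1% higher) and with each array's median as floor (39.1%). It also stayed with a floor of only 1 and no background filter (37.7%). For 130 of the higher and 224 of the lower genes a further probe set was above background on both arrays. It went the same way for 111 of the 130 and 207 of the 224, but was itself at least 2-fold apart for only 53 and 100 of them.

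**Figure D1:**
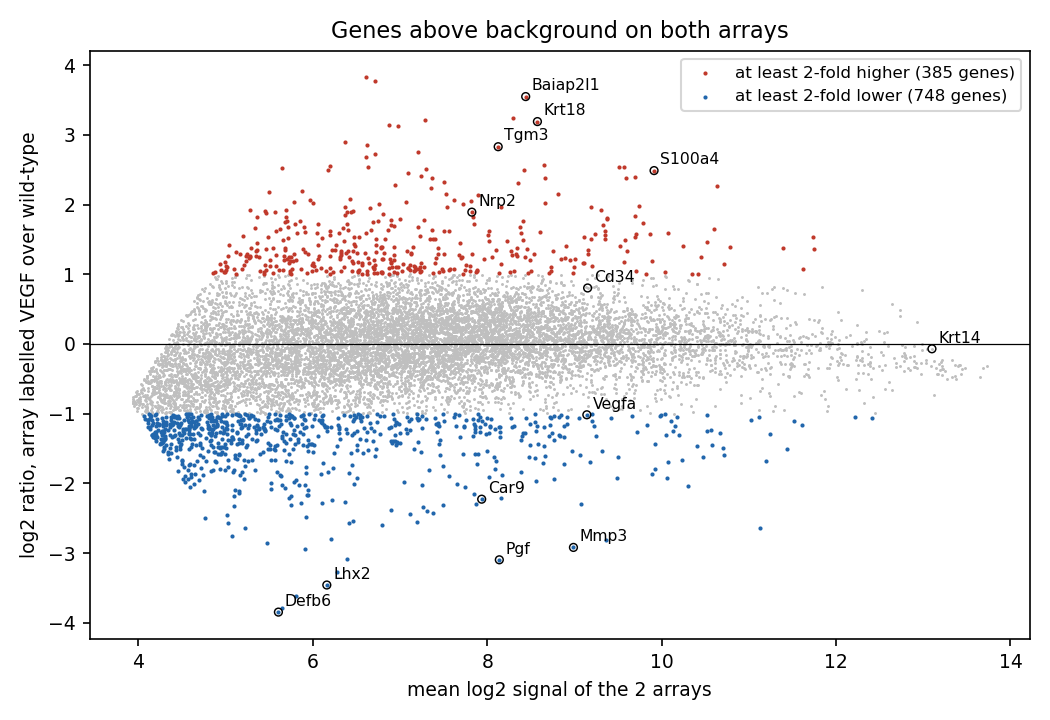
Each dot is a gene above background on both arrays. The horizontal axis is the mean log2 signal of the 2 arrays and the vertical axis the log2 ratio of the array labelled VEGF over wild-type. The 385 genes at least 2-fold higher are red, the 748 at least 2-fold lower are blue and crowd at low signal, and circled genes are named in the text.

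Vegfa itself, the gained gene, was lower on the array labelled VEGF, with a signal of 397 against 804, a log2 ratio of -1.02 where probe sets of the same gene at this signal had an SD of 0.30. The other Vegfa probe set gave -1.26. The size of the main probe set's ratio was just under 2-fold with the offset of 50 (-0.93) or with centred ratios (-0.97). It is not known here whether either probe set reads the transgene's transcript, so these values do not check the genotype label, and the directions below follow the label. Of 14 measured VEGF ligands and receptors, 1 was at least 2-fold higher and 3 were at least 2-fold lower, with a list median of 0.17 at percentile 93.5 (between 72.7 with the stricter signal filter and 99.8 with the median over each gene's probe sets). Nrp2, a VEGF and semaphorin co-receptor, was 3.71-fold higher, and its other probe sets lay between 0.80 and 2.32 on the log2 scale. Nrp1, the related co-receptor, had a signal of 127 against 67.1 (log2 ratio 0.92), with other probe sets between -0.49 and 1.06. The receptor genes Flt1 (signal 35.0 against 23.1) and Kdr (42.5 against 30.6) were close to background on the wild-type array. Sema3a was 2.41-fold lower at low signal (11.7 against 28.3), and under 2-fold with the common floor (log2 ratio -0.51).

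Cd34, Itga6 and Epcam, whose products were stained for the sort, were expressed on both arrays. Cd34 had a signal of 751 against 430 (log2 ratio 0.80), Itga6, which encodes α6-integrin, 2421 against 3952 (-0.71), and Epcam 1905 against 1597 (0.25, while the other Epcam probe set gave -1.16). Ptprc, which encodes CD45, had signals of 17.3 and 14.4, Pecam1, which encodes CD31, 22.0 and 3.07, and Pdgfra, which encodes CD140a, 34.7 and 9.86 on the array labelled VEGF and the wild-type array, each below background on the wild-type array and above the lower background of the array labelled VEGF. For Pdgfra this is at least 1.75-fold higher, while its other probe sets had signals of 12.3 against 10.2 and 10.7 against 13.7. Krt14 and Krt5, the keratins of basal epidermis, were nearly equal by their brightest probe sets (8571 against 8990, and 7875 against 8352), while the lowest of the other Krt14 probe sets gave -0.71. Of 15 measured basal keratinocyte genes, 0 were 2-fold apart, and the list median was 0.04 at percentile 65.6. Its largest ratios were those of Trp63, the basal transcription factor gene (-0.77, with other probe sets between -2.52 and -0.37), Itga6, Dst (0.53) and Sfn (0.43).

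Keratinocyte differentiation genes were higher on the array labelled VEGF. Of 20 measured, 12 were at least 2-fold higher and 0 at least 2-fold lower, with a list median of 1.13, and 0 of 10000 signal-matched random lists had a median as high. With the offset of 50 the median was 0.68, with 7 of 22 at least 2-fold higher. Besides Lce3c and Tgm3, the largest ratios were those of Cnfn, which encodes cornifelin, 5.33-fold, and Lor, which encodes loricrin of the cornified envelope, 3.60-fold. Krtdap, the most abundant member, was nearly equal (6754 against 7354). The wound and hyperproliferative list had a median of 1.15, with 12 of 20 genes at least 2-fold higher and 3 at least 2-fold lower, and 0 random lists as high. Its leading members were Krt18, a simple-epithelial keratin not specific to wounds, Sprr2f, Sprr1a and S100a9, a calprotectin subunit gene, 4.98-fold higher, while the most abundant, the wound keratin gene Krt6a, had a signal of 8752 against 10263, with other probe sets at 0.36 and 0.37 on the log2 scale. Sprr2 and Lce genes have near-identical relatives, and Lce3c was read by a probe set of the type that can bind several transcripts, so values of single members are uncertain. In the epithelial junction list, 5 of 22 genes were at least 2-fold higher and 0 lower, with a median of 0.26 at percentile 98.9. The claudin genes Cldn7 (at least 6.77-fold) and Cldn4 (5.65-fold), the desmosomal Dsc2 (5.29-fold) and the tight junction gene Ocln (3.17-fold) led it, and Dsp, the most abundant, had a log2 ratio of -0.39. Without the probe sets that can bind several transcripts this list lay at percentile 97.2.

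Hair follicle genes were lower on the array labelled VEGF. Of 26 hair follicle stem cell and bulge genes, 9 were at least 2-fold lower and 2 at least 2-fold higher, with a median of -0.46 that 0 of 10000 random lists matched. Besides Lhx2, Lgr5, a stem cell receptor and Wnt target gene, was 3.94-fold lower and Lrig1, a stem cell marker of the upper follicle, 3.90-fold lower, although 1 other Lrig1 probe set gave 0.14. Nfatc1 was 2.88-fold lower by its brightest probe set and had a median of only -0.11 over all its probe sets. Fst, which encodes the activin antagonist follistatin, was 2.61-fold higher and the most abundant of the list. Of 10 Hedgehog pathway genes, 7 were at least 2-fold lower, with a median of -1.23 and 0 random lists as low. With the offset of 50 the median was -0.59 with 1 gene at least 2-fold lower, and with the common floor it was -0.98 with 5, again with no random list as low. The 7 lower genes included Gas1, a Hedgehog co-receptor gene (2.76-fold, 818 against 2259.7), the transcription factor gene Gli2 (2.62-fold), and, at low signal, Shh (3.13-fold) and Gli1 (2.48-fold, but a log2 ratio of only -0.94 after quantile normalization). Of 16 Wnt targets, 4 were lower and 1 higher by at least 2-fold, with a median of -0.41 at percentile 3.21 (between 0.71 after quantile normalization and 19.2 with the median over probe sets). Wif1 was 6.22-fold and Lef1 2.23-fold lower, and Nkd2 4.53-fold higher by its brightest probe set, with others between -1.10 and 1.02 on the log2 scale. Of 14 Notch pathway genes, 1 was at least 2-fold higher and 0 lower, with a median of -0.12 at percentile 25.7. Notch1 was 2.06-fold higher and Notch2 had a log2 ratio of 0.96. Markers of hair shaft and inner root sheath moved alongside: 7 of 10 were at least 2-fold lower, with a median of -1.04 at percentile 0.45, among them Gata3 (2.72-fold) and, near background, Krt28 (2.89-fold), Krt27 (2.36-fold) and Msx2 (at least 3.26-fold). The hair shaft median was -0.64 with 3 of 10 at least 2-fold lower with the common floor, and -0.43 with 1 of 11 with the offset. With the common floor Shh, Gli1, Krt27, Krt28 and Msx2 were under 2-fold (log2 ratios between -0.90 and -0.53).

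Cell cycle genes were modestly higher on the array labelled VEGF. All 28 measured genes of mitosis had a ratio above 0, with a median of 0.58, and 0 random lists were as high. Of these 28, 2 were at least 2-fold higher, Nek2, a centrosomal kinase gene, at 2.23-fold and Kif23, a kinesin gene of cytokinesis, at 2.06-fold. Cdk1, the mitotic kinase gene, had a signal of 914 against 474. With the offset of 50, 0 of the 28 were at least 2-fold higher, with a median of 0.48. DNA replication genes had a median of 0.47, with 20 of 26 above 0, and 1 of 10000 random lists was as high. Rrm1, a ribonucleotide reductase subunit gene, was 2.28-fold higher, and Pcna, the most abundant, had a log2 ratio of 0.20. Ribosome biogenesis genes were above 0 in 23 of 23 cases, with a median of 0.43, 0 of them 2-fold apart and 0 random lists as high. Pes1 (0.98), Wdr12 (0.73) and Nolc1 (0.71), all of ribosomal RNA processing, had the largest log2 ratios, although the only other Wdr12 probe set with a fold gave -0.50. Ribosomal protein genes were slightly lower in 17 of 17 cases, with a median of -0.31 at percentile 0.40, but at percentile 45.1 after quantile normalization. The p53 target list had a median of 0.48 with 14 of 18 above 0, and 1 random list was as high. Its 2 genes at least 2-fold higher were Ccng1, which encodes cyclin G1 (2.38-fold), and Eda2r (at least 2.35-fold), and 1, Btg2, was 2.06-fold lower.

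Hypoxia response genes were lower on the array labelled VEGF, as Vegfa was. Of 23 measured, 7 were at least 2-fold lower and 0 higher, 21 had a ratio below 0, the median was -0.75, and 0 of 10000 random lists were as low. Car9, which encodes the hypoxia-induced carbonic anhydrase IX, was 4.68-fold lower, Egln3, a prolyl hydroxylase gene induced by hypoxia, 3.25-fold, Bnip3, of mitophagy, 3.07-fold, and Pdk1, which encodes a kinase that restrains pyruvate dehydrogenase, 3.06-fold. Ldha, the most abundant, was nearly equal (6640 against 7584). Immediate early genes, which respond to growth factors and also to tissue dissociation, were lower as well. Of 25, 6 were at least 2-fold lower and 0 higher, with a median of -0.67 and 0 random lists as low (median -0.44 without probe sets that can bind several transcripts). The largest ratios were those of Egr2 (5.38-fold lower), Egr3 (3.78-fold), Jund (3.21-fold) and the heat shock gene Hspa1a (2.39-fold), while Fos had a signal of 6942 against 9373. In the list of ERK pathway outputs and EGFR ligands the median was -0.36, with 6 of 10000 random lists as low, 1 of 20 genes at least 2-fold lower (the feedback inhibitor gene Spry4, 24.2 against 72.6) and 1 at least 2-fold higher (the EGFR ligand gene Ereg, 2.22-fold).

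Matrix remodelling genes went both ways, with a low list median. Of these, 6 of 20 were at least 2-fold lower and 3 at least 2-fold higher, with a median of -0.33 at percentile 0.26, and at percentile 5.50 with the offset of 50. Mmp3, Mmp10 (4.91-fold) and the collagenase gene Mmp13 (4.10-fold, 623 against 2555) were lower, and Timp1, which encodes a metalloproteinase inhibitor, was 4.70-fold higher. Genes of mesenchymal transition went both ways, with a median of 0.01 at percentile 71.9, 4 of 15 at least 2-fold higher and 2 lower. S100a4, which encodes a calcium-binding protein linked to motility, was 5.61-fold higher (2284 against 407), Hmga2, a chromatin protein gene of early development, 3.25-fold, and the transcription factor genes Twist2 3.76-fold and Twist1 at least 3.29-fold. The fibroblast list, which also holds Twist2, was higher on the same array (median 0.76). Inflammatory cytokine genes had a median of 0.01 at percentile 57.9, with 5 of 26 at least 2-fold higher, led by Tslp, an epithelial cytokine gene (5.21-fold), Cxcl3 (4.16-fold), Csf3 (2.60-fold) and Ccl2 (2.61-fold), and 1 lower. Interferon response genes had a median of -0.05 at percentile 61.6, with 0 of 17 at least 2-fold higher and 1 lower, Oas3, which was under 2-fold with the common floor (log2 bound -0.29). In the list of stem cell factors and drug transporters the median was 0.25 at percentile 95.5, with 4 of 15 at least 2-fold higher and 3 lower. Its largest ratios were those of Aldh1a3, an aldehyde dehydrogenase gene (5.87-fold by its brightest probe set, log2 ratios of 0.46 and 1.05 by the others), Prom1, which encodes CD133 (3.11-fold), Sox2, a stem cell transcription factor gene (2.53-fold, 685 against 271), and Pitx1 (2.46-fold).

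Of the metabolic and stress lists, the NRF2 targets had a median of 0.35 at percentile 99.4 with 2 of 17 genes at least 2-fold higher, Slc7a11 and Gsta2 (2.34-fold). Of the 17, 5 lay below 0, among them the glutathione transferase genes Gstm1 (-0.95) and Gstm2 (-0.93). The unfolded protein response list had a median of 0.34 at percentile 99.7, and at percentile 92.5 with the median over probe sets. It held 2 genes at least 2-fold higher, Asns, which encodes asparagine synthetase (2.25-fold), and Chac1 (2.01-fold, near background), while 8 of 20 lay below 0, Dnajb9 lowest at -0.70. Cholesterol synthesis (median 0.17, percentile 82.8), oxidative phosphorylation (0.04, percentile 82.8) and AhR targets (0.32, percentile 87.7, only 5 genes measured) lay within the range of random lists. Of these 3 lists, the genes at least 2-fold higher were Mvk, which encodes mevalonate kinase (2.41-fold), and Ndufa4 (2.91-fold, 5833 against 2006).

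**Figure D2:**
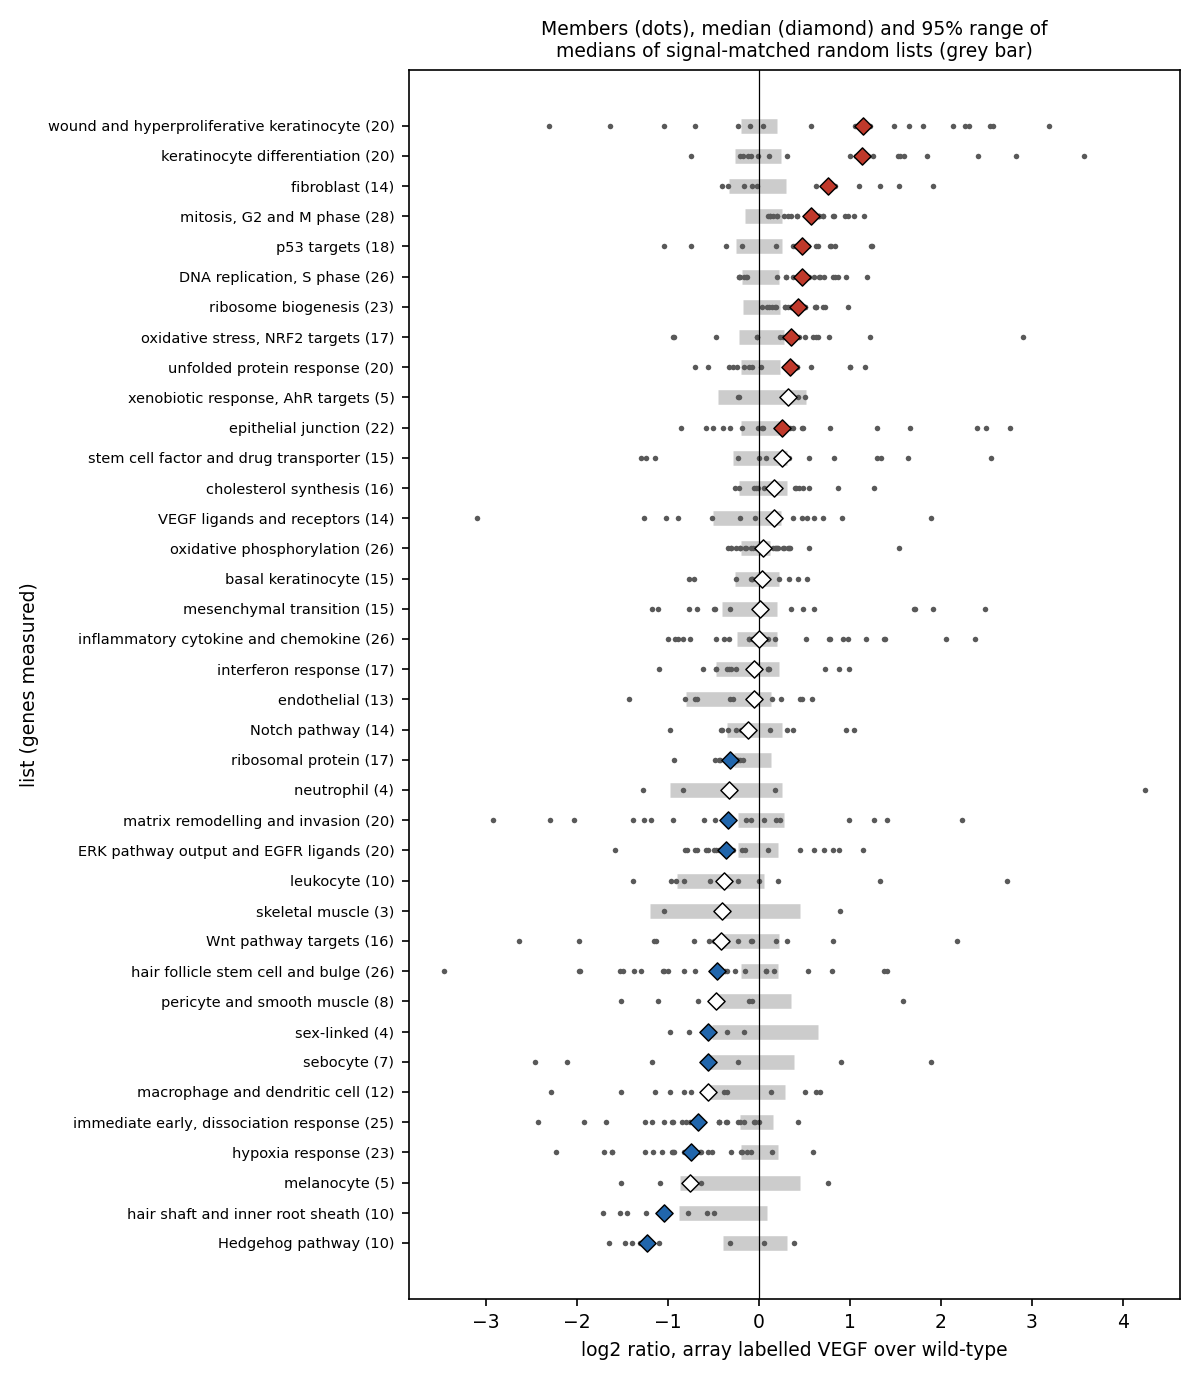
Each line is a fixed list of at least 3 measured genes, with the number of measured genes in brackets, ordered by its median. Dots are members, diamonds medians and grey bars span the medians of signal-matched random lists without the outer 2.5% on each side, on the log2 ratio of the array labelled VEGF over wild-type. Red and blue diamonds lie above and below that range, and of these lists the Hedgehog list lies lowest, at -1.23.

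Among markers of other cell types, fibroblast genes were higher on the array labelled VEGF, although the cells had been stained for CD140a before sorting. The list median was 0.76, with 4 of 14 genes at least 2-fold higher, 0 lower and 0 random lists as high. Of the 14, 9 lay above 0 and 5 below. Col1a2 (942 against 324, 2.91-fold), Col3a1 (1235 against 489.9, 2.52-fold) and Col6a3 (2.14-fold), all collagen genes, were higher, as was Twist2, and Sparc, the most abundant, had a log2 ratio of 0.73 with other probe sets between -1.81 and 1.14. The leukocyte list had a median of -0.38 at percentile 60.2, with Lcp1 at least 6.64-fold and Coro1a 2.51-fold higher and Cd52 at least 2.61-fold lower (log2 bound -0.58 with the common floor). Of its 10 measured members 5 were bounds, and with no floor the median over 15 members was 0.03 at percentile 89.3. Macrophage and dendritic cell genes had a median of -0.56 at percentile 2.83. The antigen presentation genes H2-Eb1 and H2-Aa were 4.89- and 2.86-fold lower, with other H2-Aa probe sets between -2.08 and -1.26 on the log2 scale. H2-Ab1, of the same function, had a signal of 194 against 137, with other probe sets between -0.82 and 0.13 on the log2 scale. The main H2-Aa and H2-Ab1 values come from probe sets that can bind several transcripts. Endothelial genes (median -0.06, percentile 78.9) had 1 of 13 at least 2-fold lower, Aplnr (log2 ratio -0.78 with the common floor), and the brightest, Eng, had signals of 54.4 and 66.4. Pericyte genes (median -0.47, percentile 3.11, with Acta2 2.15-fold lower and Mcam higher at 169 against 56.4), melanocyte genes (-0.75, percentile 5.05, with Dct 2.86-fold lower), neutrophil genes (-0.32, percentile 49.4, 4 measured, with Ltf at least 18.9-fold higher and Il1r2 2.42-fold lower) and skeletal muscle genes (-0.40, percentile 30.3, 3 measured) lay within the range of random lists. Sebocyte genes had a median of -0.56 at percentile 2.24, with Elovl3 5.50-fold and Far2 at least 4.30-fold lower (3.82-fold and at least 2.46-fold with the common floor) and Fads2 3.71-fold higher, but with a mean signal of at least 4 times background the median was 0.34 over 4 genes. Of the T and NK cell, mast cell, adipocyte and erythroid lists, 2, 1, 1 and 0 members were measured, all 4 at least 2-fold lower, among them Fabp4 (2.84-fold, 1649 against 4689), although the mast cell marker Kit was under 2-fold with the common floor (log2 bound -0.45). The Y-linked genes Eif2s3y (312 against 398), Kdm5d (59.5 against 117) and Uty (69.9 against 119) were above background on both arrays. So was Xist, the X inactivation transcript (124 against 138), with other probe sets nearer background (26.4 against 27.5, and 12.5 against 22.8). Why Y-linked genes and Xist were both read on each array was not tested. The sex-linked list pools them, so its median does not read the sex of the animals. The sex-linked list had a median of -0.56 at percentile 1.82, but lay at 2.51 with the median over probe sets and at 3.84 without _x_at and _s_at probe sets.

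RNA and hybridisation controls also differed between the arrays. With 1 array per genotype, such differences cannot be told apart from genotype for any gene or list given here. The 3′ to 5′ signal ratio of the Actb control was 1.45 on the array labelled VEGF and 2.01 on the wild-type array, and that of the Gapdh control 0.912 and 1.15. The 18 hybridisation control probe sets had a median log2 ratio of -0.50 and the 24 polyadenylated spike-in probe sets one of -0.90, while the 11233 genes had a median of -0.04. Of 38 lists with a percentile, 20 lay outside the range of random lists (10 on each side). The number would be 1.9 if genes of a list behaved like randomly drawn genes, which genes regulated together do not.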

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

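Except for the tests of the second hypoxia and fibroblast sets, whose members and predictions were written before their values were seen, the tests in this part were chosen after the results were seen.

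Outside the named genes, 2410 probe sets with no gene in the annotation were above background on both arrays. Of these, 34 were at least 2-fold higher and 645 at least 2-fold lower on the array labelled VEGF. Among the 11233 genes above background on both arrays the numbers were 385 and 748. The higher share was thus smaller, and the lower share larger, among the probe sets with no gene. The 3′ probe set of the 18S ribosomal RNA control, also outside the comparisons, had a log2 ratio of 1.11, and the median over the 3 such probe sets was 0.53.

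Vegfa and the hypoxia response genes were lower on the array labelled VEGF. A scaling difference between the arrays is argued against for the hypoxia list, relative to other genes of the same signal. Under the main setting and all 10 alternatives the list median lay below the 2.5th percentile of signal-matched lists. The distance was at least 0.40 on the log2 scale (gap -0.40). Vegfa by itself was not covered by this test. No setting scaled the arrays to the hybridisation and polyadenylated controls, which were lower too (median log2 ratios -0.50 and -0.90). A lower hypoxia response in these cells predicted that the second, non-overlapping hypoxia set would also be low, and its 36 measured genes had a median of -0.52, with 0 of 10000 random lists as low. A different response to tissue handling stays open beside it, since immediate early genes were low too (median -0.67). An exchange of the labels of the arrays and the presence of the transgene were not tested, as no gene here is known to read the transgene.

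The fibroblast list, with 3 collagen genes at least 2-fold higher, was higher on the array labelled VEGF, although the cells had been stained for CD140a before sorting. Collagen genes as a family, grouped by symbol alone, were not: of 30 measured, 4 were at least 2-fold higher and 5 lower (median -0.17, percentile 28.4). The family also holds collagens outside the fibroblast list, such as Col18a1 of the bulge list, so it is no test of the fibroblast collagens. If more fibroblast RNA were the cause, the second set of fibroblast genes should have been high as well, and its 21 measured genes had a median of 0.11 at percentile 85.4. That prediction was not met. Its members went both ways (12 above 0, 9 below, SD 1.02), and the set showed no rise like the 0.76 of the first list. A smaller rise, within the range of random medians (-0.36 to 0.25), would not have shown, so a smaller amount of fibroblast RNA is not excluded. Mesenchymal expression of the tumour cells predicted a high mesenchymal transition list, which lay at percentile 71.9 with 8 members above 0 and 7 below. That prediction was not met either, and a rise within the random range or of single members is not excluded.

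More genes were at least 2-fold lower than higher on the array labelled VEGF. A different low end of the signal scale on the arrays fits: with a mean signal of at least 4 times background 49.9% of the genes 2-fold apart were higher. The gap between the background floors (19.8 and 11.3) is part of it by construction, since with a common floor the lower genes numbered 624 and not 1041. For the probe sets with no gene it is open whether the low end is the whole account. Their median log2 ratio was 0.30 lower (-0.30) than that of named probe sets of the same signal, and outside all 1000 matched draws. Matching on mean signal does not match the share of probe sets that read little but background. The draws therefore cannot tell the low end from a second difference between the RNA samples or the labelling.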

How the results depend on the processing

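The 472 higher genes became 1675 with no floor and no filter, 184 with the offset of 50 and 297 with the stricter signal filter. The 1041 lower genes became 2770 with no floor, 169 with the offset, 596 after quantile and 565 after loess normalization, 298 with the stricter filter and 624 with a common floor (the last chosen after seeing the data). Of the 1041, 581 were called after quantile and 559 after loess normalization, and of the 472 higher genes 454 and 461 were. The SD of the difference between probe sets of the same gene was 0.60 above background and 1.43 over all gene probe sets. Of the 20 lists apart from random lists, 13 stayed apart on the same side under all 10 alternatives: differentiation, wound, bulge, replication, mitosis, hypoxia, immediate early, ERK, Hedgehog, p53, NRF2, ribosome biogenesis and fibroblast. Hair shaft genes stayed apart in the 9 alternatives that gave a value; the stricter filter left too few members. Lists that lost the call were epithelial junction (percentile 97.2 without _x_at and _s_at probe sets), matrix remodelling (5.50 with the offset), unfolded protein response (92.5 with the median of probe sets), ribosomal protein (45.1 quantile, 2.54 loess, 2.65 median of probe sets), sex-linked (2.51 median of probe sets, 3.84 without _x_at and _s_at) and sebocyte (2.87 array median as floor, 8.81 offset, 6.10 quantile, 6.58 loess, 4.50 median of probe sets, 4.37 common floor). Sebocyte genes reversed with the stricter filter (percentile 88.2), which leaves 4 of the 7 genes. Lists that gained a call were VEGF ligands and receptors (99.5 array median as floor, 99.8 median of probe sets, 99.2 without _x_at and _s_at), Wnt targets (2.38 offset, 0.71 quantile, 1.26 loess), stem cell factors (98.4 offset), macrophage (0.97 offset, 2.20 quantile, 1.85 loess, 2.27 without _x_at and _s_at) and melanocyte (0.67 stricter filter, 0.89 common floor). With the common floor 12 fixed lists had fewer genes at least 2-fold lower. Apart from the fewer genes under the filters, the cause was not tested. No named gene at least 2-fold apart changed direction: of 2027 values of named genes under the alternatives, 91 fell under 2-fold and 32 passed it. No paired analysis was possible because each group has 1 array, and for the same reason no replicate could be left out. Signal over background limits the genes near the floor, where the SD of a probe set's log2 ratio is 0.51 and a 2-fold change is under 2 SDs.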

Other observations

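Gene families were also compared, by the stem of their symbols, in 188 families with at least 8 measured members; this was chosen after seeing the data, as were the genes named here. Of these, 33 lay in the outer 2.5% on either side of signal-matched random lists. The number would be 9.4 if members of a family behaved like randomly drawn genes, which related genes need not do. Several Sprr and Mmp genes, Serpinb2 and Zfp36 are also in the fixed lists. Upward shifts were seen in the small proline-rich proteins of the cornified envelope (Sprr), with 8 of 8 at least 2-fold higher and a median of 2.18, and in the clade B serpins (Serpinb), protease inhibitors abundant in epidermis, with 3 of 12 at least 2-fold higher and a median of 0.74. Serpinb2 was at a signal of 3495 against 724 and Serpinb1a at 565 against 219.8. Carboxylesterases (Ces) had 4 of 8 at least 2-fold higher, though the family lay at percentile 77.8 with the stricter signal filter, which left 3 of them, and mitochondrial ribosomal proteins of the small subunit (Mrps) had a median of 0.35 with 0 of 29 at least 2-fold apart.

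Downward, the Frizzled receptors of Wnt ligands (Fzd) had a median of -0.93, with 3 of 9 at least 2-fold lower. Fzd1 was at 266 against 662 and Fzd7 at 174 against 394, while Fzd6 was nearly equal at 598 against 642. Matrix metalloproteinases (Mmp) had 6 of 10 at least 2-fold lower and a median of -1.22, and of -0.53 with the offset of 50. Zinc finger proteins (Zfp) had a median of -0.33 over 242 genes, and of -0.12 after loess normalization, and lysine methyltransferases (Kmt) one of -0.60 over 8 genes with 0 at least 2-fold apart. No family named here changed the sign of its median under the other settings.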
